A study of Rattus norvegicus with 6 samples.

How the data were processed

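The data were 6 RNA-seq libraries of rat myocardial tissue, 3 of an acute myocardial infarction model (MOD 1 to 3) and 3 of the same model with XHT (XHT 1 to 3). Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT) beads, and libraries were made with a dUTP second strand and adapters that carried unique molecular identifiers. Sequencing was paired-end on an Illumina NovaSeq instrument, per the labels. Poly(A) selection leaves transcripts without a tail under-represented, and whether the identifiers were used to collapse PCR copies is not given in the sources used here.

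The authors deposited one table with raw counts and FPKM per gene and library and their own comparison. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.16.1 were used; their order and settings, whether counting used the strand, and the genome build are not given in the sources used here. Per the file headers, the count columns hold counts per gene, and their values are whole numbers with totals that differ between libraries. Per the file headers, the FPKM columns are in FPKM; their values equal counts divided by gene length and by a library constant proportional to DESeq2's size factor, so the deposited FPKM values were already scaled between libraries and were not tested. The deposited MOD group means, a signal scale, equal the mean of counts over size factors, and those of XHT were not checked. The log2 fold changes and p-values of the comparison are the authors', per the file headers; the deposited adjusted p was 1 for 2730 genes, 57 of which had no p-value. These columns were used only to describe the authors' comparison.

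Differential expression was computed from the deposited counts in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr (minimum count 10, minimum total 15), a robust quasi-likelihood fit of XHT against MOD without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. TMM factors were 1.12, 1.23 and 1.10 in MOD 1, 2 and 3 and 0.87, 0.92 and 0.83 in XHT 1, 2 and 3, so the choice of scaling bears on the balance of higher and lower genes. CPM values are TMM-normalised, and log2 CPM used a prior count of 2. No library pair was a duplicate: the smallest chi-square per degree of freedom between libraries was 46.0.

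On the TMM-normalised scale, a count of 0 in 1 library allows up to 3 counts, which is 0.148 to 0.204 CPM in the 6 libraries; ratios to a group with 0 counts use 3 counts over the group. These limits cover counting error only. The common biological coefficient of variation was 0.348. The pipeline was tested on simulated data: of 100 genes changed 2-fold in a simulated XHT against MOD comparison of 14488 genes, 6% were called, and of 100 changed 4-fold, 53%, all with the right sign, with 7 unchanged genes called. Far fewer genes were changed there than the 4128 called in the data, so the Benjamini-Hochberg cut on p was stricter in the simulation. These shares therefore do not give the share of changed genes found in the data. The simulated changed list was called and 0 of the other lists were. Simulated genes varied independently of each other, whereas the estimated correlation within lists reached 0.99 in the data, for oxidative phosphorylation. The simulation therefore cannot show how often camera with the preset correlation passes an unchanged list here.

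Gene lists (35, covering programs of infarcted heart, handling and time of day, and markers of other cell types) and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls among genes past the threshold with a symbol, a mean log2 CPM of at least 1 and no overlap between groups, up to 4 called members per list by lowest p, 14 genes given whatever their test, and the 5 genes of lowest p in each direction. Genes outside the rule are said to be singled out where they appear. Lists were tested with camera and fry in limma 3.58.1, with a preset correlation of 0.01 for camera; fry tests whether a list's genes moved on balance in one direction and does not compare them with other genes. A symbol with several identifiers was represented by the one with most counts, and list genes without a tested identifier under their symbol were not analysed here. Genes that share reads with a near-identical copy, such as Fam134b, are uncertain.

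The alternatives were DESeq2 size factors, no count filter, the replicate number as a block, the legacy quasi-likelihood fit, protein-coding genes only, DESeq2 1.42.0 (Wald test), each library left out in turn, and for lists an estimated correlation and fry. Scaling to total counts and leaving out genes of the mitochondrial genome were added after the data were seen. The alternatives written for FPKM alone were not needed, since counts were deposited. Values of a few genes are not reported here. No reference genome was used.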

Results

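RNA of myocardial tissue from Sprague-Dawley rats was sequenced in 6 libraries, 3 from a rat model of acute myocardial infarction (MOD) and 3 from the same model given XHT. The series title names the preparation as Xinhuitong and ties it to coronary heart disease. The comparison addressed which transcripts differed in infarcted hearts given the preparation. The labels gave neither the dose, the time after infarction, the part of the heart sampled nor whether each library came from a separate animal. The p-values therefore measure the spread between these samples, which may not be that between animals. This spread exceeded counting error, with a chi-square per degree of freedom of at least 46.0 for every pair of libraries. Total counts per library lay between 16550007 and 17724689, and 14488 of the 33509 genes in the table had enough counts to be tested.

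In the XHT libraries, 29 of 32 tested matrix genes, 13 of 17 macrophage markers and 15 of 21 cell cycle genes were lower than in MOD. Higher were 14 of 27 fatty acid oxidation genes, 7 of 25 oxidative phosphorylation genes, 7 of 23 calcium handling and ion channel genes and 5 of 12 cardiac stress genes. In these 4 lists, as in the sarcomere list, the mean log2 CPM was higher in MOD 3 than in MOD 1 and MOD 2 and higher still in every XHT library. As lists, all 7 passed a test with a preset correlation between genes and none passed with an estimated one. Col1a1, the main chain of type I collagen, fell from 13410 ± 6678 CPM in MOD to 210.3 ± 277.2 CPM in XHT (SD, n = 3 each). Postn, a matrix protein of activated fibroblasts, fell from 4945 ± 3054 to 50.0 ± 59.9 CPM. Pdk4, the kinase that limits pyruvate oxidation, rose from 11.7 ± 8.02 to 701.1 ± 390.8 CPM. Cd36, a fatty acid transporter, rose from 131.9 ± 95.9 to 750.1 ± 115.9 CPM. At an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1792 genes were higher and 2336 lower in XHT, 28.5% of those tested, and 3151 of the 4128 differed by more than 2-fold. The 3 values of one group lay wholly above the 3 of the other for 51.3% of the tested genes, where chance gives 10% on average. Genes vary together, so the share in a single split can lie far from that average, and it was not counted for other splits.

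The size of this count rested on single libraries. Without XHT 1 the same test called 4 genes higher and 4 lower, and without XHT 3 it called 148 and 288. Without MOD 1 it called 128 and 375, without MOD 2 it called 227 and 570, and without MOD 3 it called 3487 and 3421. The split between directions depended on scaling: with libraries scaled to their total counts, an alternative added after the data were seen, 925 genes were higher and 4320 lower, and the median log2 fold change of all genes moved from -0.02 to -0.42.

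The libraries did not fall into even groups of 3. On the first principal component, which held 74.4% of the variance, MOD 1 and MOD 2 lay at -98.5 and -105.7, MOD 3 at -19.8, and XHT 1, 2 and 3 at 87.4, 46.1 and 90.4. Across genes, which are not independent replicates, the Spearman correlation was 0.954 between MOD 3 and XHT 2 and 0.931 between MOD 3 and MOD 1. Genes of the mitochondrial genome took 20.4% ± 4.23 of the counts in MOD and 28.1% ± 1.52 in XHT (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

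Among the genes with the largest falls, Capn6, a calpain family member without protease activity, had 2050 counts in the MOD libraries and 3 in the XHT libraries, a ratio of 532 with a 95% exact counting interval of 182 to 2582 that covers counting error only. Cthrc1, a secreted collagen-region protein, fell from 411.6 ± 234.9 to 2.00 ± 2.19 CPM. Tnc, the matrix protein tenascin C, fell from 560.1 ± 480.1 to 4.38 ± 6.48 CPM, and Mmp12, the macrophage elastase, fell from 72.2 ± 10.4 to 0.48 ± 0.83 CPM (SD, n = 3 each). C1qtnf3, Wisp1, Tnn and Car3 also fell, by 7.99, 7.32, 7.20 and 6.99 on the log2 scale. Kcna6 had 385 counts in MOD and 1 in XHT, a ratio of 300 with an interval of 53.5 to 11868, and Adamts16 had 331 and 1, a ratio of 258 with an interval of 45.9 to 10208. All of these passed edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p-values from 3.98e-05 for Capn6 to 0.0221 for Tnc.

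Among the genes with the largest rises, Cyp2e1, a cytochrome P450 enzyme, rose from 0.29 ± 0.31 to 39.0 ± 33.8 CPM, and Abra, an actin-binding protein of striated muscle, from 7.96 ± 11.2 to 604.2 ± 488.5 CPM (SD, n = 3 each). Klhl40, a muscle thin filament stabiliser, rose by 5.78 ± 1.12 (log2 fold change ± SE), and Gal, the neuropeptide galanin, by 6.39 ± 0.61. Myl7, the atrial myosin light chain, stood at 3.19, 57.4 and 45.0 CPM in XHT 1, 2 and 3 and between 0.16 and 0.57 CPM in MOD. Echs1, an enzyme of fatty acid oxidation, owed its group mean of 37.9 CPM to XHT 3, where it stood at 109.8 CPM against 2.59 in XHT 1 and 1.32 in XHT 2. Fam134b, a receptor of endoplasmic reticulum turnover, was listed under 2 identifiers that both rose, by 6.60 and 4.11 on the log2 scale, and reads shared between the copies leave each value uncertain. Adjusted p-values of these genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.00717 for Fam134b to 0.0404 for Echs1.

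Of 35 gene lists fixed before the data were examined, 16 passed the threshold in limma's camera test with a preset correlation of 0.01, 8 of them higher and 8 lower in XHT. None of the 16 passed with an estimated correlation between genes, where the adjusted p was 0.607 for 15 of them and 0.768 for interferon response. Without XHT 1, 0 members of the 16 lists were called. By limma's fry test, 4 lists passed: extracellular matrix, macrophage, antioxidant, and the coagulation list, which had not passed camera. With the preset correlation, splits that mixed MOD and XHT libraries also gave between 8 and 16 lists past camera, with 0 genes called.

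**Figure D1:**
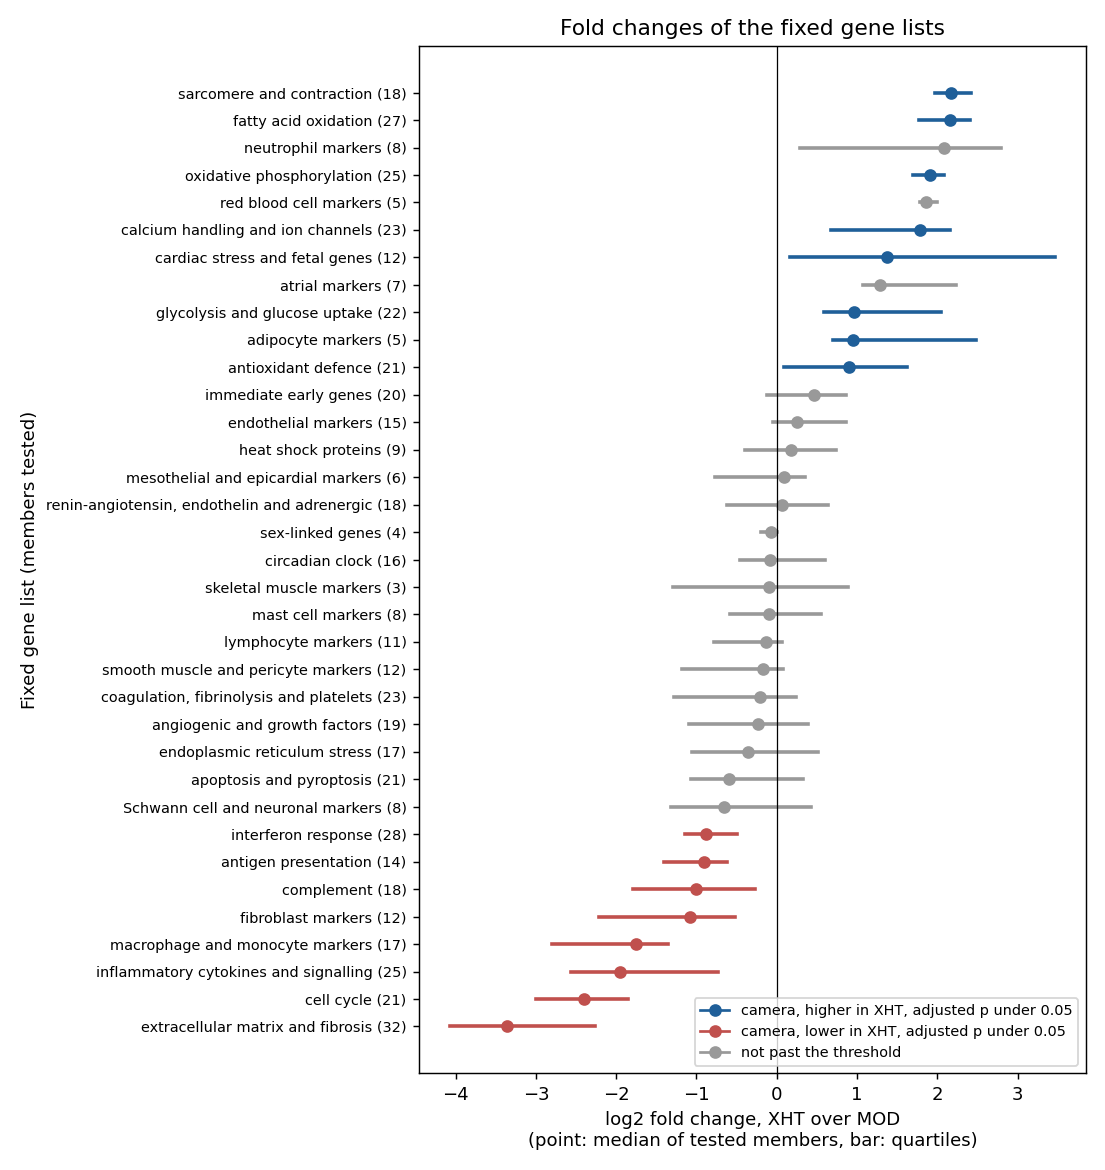
Log2 fold change of XHT over MOD for the 35 gene lists, with the number of tested members in parentheses. Points are medians over members and bars run between the quartiles; blue marks lists higher and red lists lower in XHT by camera with the preset correlation, and grey the others. The medians ran from -3.36 for extracellular matrix to 2.16 for sarcomere genes.

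Of the 32 extracellular matrix and fibrosis genes, 29 fell, 0 rose, and the median log2 fold change was -3.36 (camera adjusted p = 3.53e-13; adjusted p = 0.607 with an estimated correlation; fry adjusted p = 0.0479). Adjusted over the list alone, 30 fell. Col3a1, a fibrillar collagen, fell from 21365 ± 9077 to 622.1 ± 818.6 CPM, and Eln, the elastic fibre protein elastin, from 2563 ± 1378 to 133.6 ± 40.1 CPM (SD, n = 3 each). Fap, a surface protease of activated fibroblasts, fell from 129.7 ± 60.6 to 7.82 ± 2.37 CPM (SD, n = 3 each). Tgfb3, a fibrogenic growth factor, fell by 2.47 ± 0.28 on the log2 scale. XHT 2 carried most of the XHT mean of Col1a1, at 530.0 CPM against 64.4 in XHT 1 and 36.4 in XHT 3. The same held for Col3a1 (1567 against 175.9 and 123.6 CPM) and Postn (118.2 against 5.72 and 26.1 CPM). These XHT 2 values lay below the lowest MOD values of 5931, 10961 and 1611 CPM, all in MOD 3. The number of matrix genes called was 10 without MOD 1, 18 without MOD 2, 0 without XHT 1 and 5 without XHT 3.

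Of 12 fibroblast markers, 6 fell, among them Lum, a collagen-binding proteoglycan (log2 fold change -3.95 ± 0.66 SE), and Mfap5 (-3.16 ± 0.58), and 1 rose, Gsn, an actin-severing protein singled out after its values were seen (camera adjusted p = 0.0228; adjusted p = 0.607 with an estimated correlation). With libraries scaled to total counts the fibroblast list no longer passed (adjusted p = 0.0738). The number that fell was 1 without MOD 1, 3 without MOD 2 and 0 without XHT 1 or XHT 3.

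Of 17 macrophage and monocyte markers, 13 fell (camera adjusted p = 1.20e-06; adjusted p = 0.607 with an estimated correlation; fry adjusted p = 0.0473). Cd68, a lysosomal protein of macrophages, fell from 89.4 ± 35.5 to 12.8 ± 3.99 CPM. Gpnmb fell from 408.0 ± 87.2 to 44.1 ± 14.2 CPM, and Trem2, a lipid-sensing receptor, from 60.1 ± 26.0 to 5.96 ± 1.99 CPM (SD, n = 3 each). The 1 marker that rose was Cd163, the haemoglobin scavenger receptor, which was singled out after its values were seen (log2 fold change 1.01 ± 0.23 SE). The number that fell was 9 without MOD 1, 10 without MOD 2, 0 without XHT 1 and 8 without XHT 3.

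Of 25 inflammatory cytokine and signalling genes, 11 fell and 0 rose (median log2 fold change -1.95; camera adjusted p = 0.00124; adjusted p = 0.607 with an estimated correlation). The number that fell was 2 without MOD 1, 3 without MOD 2, 0 without XHT 1 and 1 without XHT 3. Il1rn, the interleukin 1 receptor antagonist, fell by 2.88 ± 0.57 on the log2 scale, Sele, an endothelial adhesion molecule, by 2.66 ± 0.51, and Tlr2, a receptor for microbial lipoproteins, by 2.14 ± 0.27. Il1b stood at 8.07 ± 10.5 CPM in MOD and 4.85 ± 2.94 in XHT, and Ccl2 at 17.0 ± 13.3 and 3.66 ± 3.90 CPM (SD, n = 3 each), with adjusted p-values of 0.589 and 0.0829 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Il6 was not tested, with 73 counts over the 6 libraries, 47 of them in MOD 2.

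Of 18 complement genes, 9 fell, such as C5ar1, the receptor for C5a (log2 fold change -1.94 ± 0.33 SE). The complement inhibitor Cd55, singled out after its values were seen, rose (camera adjusted p = 0.00315; adjusted p = 0.607 with an estimated correlation). The number of complement genes that fell was 1 without MOD 1, 2 without MOD 2 and 0 without XHT 1 or XHT 3. Of 14 antigen presentation genes, 5 fell, among them RT1-Da and Cd80, and 1 rose, RT1-DMb, from 0.55 ± 0.12 to 6.37 ± 1.08 CPM (SD, n = 3 each; camera adjusted p = 0.0296; adjusted p = 0.607 with an estimated correlation). The number of antigen presentation genes that fell was 0 without MOD 1, XHT 1 or XHT 3 and 1 without MOD 2. The antigen presentation list did not pass camera without MOD 3 (adjusted p = 0.0727), without XHT 1 (0.0618) or with scaling to total counts (0.0738). With that scaling, however, 9 of its genes fell, and its median log2 fold change was -1.29 against -0.91 in the main fit. Of 28 interferon response genes, 3 fell, Gbp2, Ifi44 and Psmb9, and 0 rose (camera adjusted p = 0.00994; adjusted p = 0.768 with an estimated correlation). With scaling to total counts, 11 fell, and without MOD 1, XHT 1 or XHT 3, 0 fell. This list did not pass without MOD 3 (adjusted p = 0.236), where its median log2 fold change went from -0.89 to -0.23, or without XHT 3 (0.0943). Its mean log2 CPM was 4.87, 4.55 and 5.72 in MOD 1, 2 and 3 and 4.33, 4.94 and 3.69 in XHT 1, 2 and 3, so the groups overlapped.

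Of 21 cell cycle genes, 15 fell and 0 rose (median log2 fold change -2.40; camera adjusted p = 4.83e-07; adjusted p = 0.607 with an estimated correlation). The number that fell was 1 without MOD 1, MOD 2 or XHT 3, 0 without XHT 1, 19 without MOD 3 and 18 without XHT 2. Mki67, a marker of dividing cells, fell from 37.3 ± 17.5 to 4.07 ± 3.14 CPM, and Mcm5, a subunit of the replicative helicase, from 20.7 ± 4.01 to 3.93 ± 0.46 CPM (SD, n = 3 each).

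Of 27 fatty acid oxidation genes, 14 rose and 0 fell (median log2 fold change 2.16; camera adjusted p = 3.98e-09; adjusted p = 0.607 with an estimated correlation), and 24 rose when adjusted over the list alone. The number that rose was 2 without MOD 1, MOD 2 or XHT 3, 0 without XHT 1, 25 without MOD 3 and 8 without XHT 2. MOD 3 stood apart here too, with a mean log2 CPM over the list of 6.55 against 4.72 and 4.25 in MOD 1 and MOD 2. Beside Pdk4 and Cd36, Cpt1a, a gate of fatty acid entry into mitochondria, rose by 1.53 ± 0.20 and Etfa, an electron transfer flavoprotein subunit, by 2.11 ± 0.50 (log2 fold change ± SE). Cpt1b, the muscle form of the same gate, rose from 55.3 ± 68.1 to 434.8 ± 71.4 CPM (SD, n = 3 each). Of 25 oxidative phosphorylation genes, 7 rose and 0 fell, and 23 rose when adjusted over the list alone (camera adjusted p = 1.62e-08; adjusted p = 0.607 with an estimated correlation). Without MOD 1, MOD 2, XHT 1 or XHT 3 the number that rose over all genes was 0, without XHT 2 it was 2, and without MOD 3 all 25 rose. The mean log2 CPM over this list was 6.68, 6.55 and 8.79 in MOD 1, 2 and 3. Sdha, a subunit of respiratory complex II, rose from 187.2 ± 156.7 to 897.3 ± 206.7 CPM, and Uqcrc2, of complex III, from 113.4 ± 108.4 to 685.6 ± 111.3 CPM. Of 22 glycolysis and glucose uptake genes, 5 rose, among them the lactate transporter Slc16a1 (log2 fold change 2.06 ± 0.47 SE), and 1 fell, the lactate exporter Slc16a3 (-1.51 ± 0.34; camera adjusted p = 7.15e-05; adjusted p = 0.607 with an estimated correlation). The number of glycolysis genes that rose was 17 without MOD 3, 1 without MOD 1, MOD 2 or XHT 3, 0 without XHT 1 and 2 with scaling to total counts. The mean log2 CPM over this list was 7.07 in MOD 3 against 5.79 and 5.85 in MOD 1 and MOD 2, and 7.49 to 7.82 in XHT.

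All 18 tested sarcomere and contraction genes had a positive log2 fold change, with a median of 2.16. Of these, 1 passed over all genes (camera adjusted p of the list = 2.12e-06; adjusted p = 0.607 with an estimated correlation). Without MOD 3, all 18 were called higher. The number was 0 without MOD 1, MOD 2, XHT 1 or XHT 3, 1 without XHT 2, and 13 with the replicate block. Over the sarcomere list, the mean log2 CPM was 7.15 in MOD 1, 6.94 in MOD 2 and 10.2 in MOD 3, against 11.4, 10.8 and 11.3 in XHT 1, 2 and 3. Myh7, the slow myosin heavy chain, stood at 1079 ± 1491 CPM in MOD and 15235 ± 8950 in XHT, and Myh6, the fast chain, at 1346 ± 1885 and 5799 ± 3666 CPM (SD, n = 3 each). Neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0592 and 0.196).

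**Figure D2:**
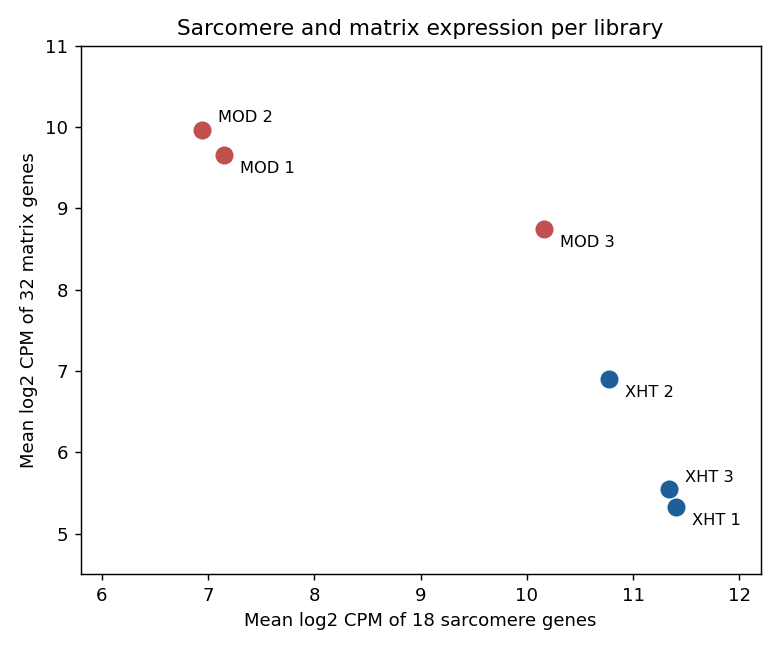
Mean log2 CPM of 18 sarcomere genes against that of 32 extracellular matrix genes, 1 point per library, MOD in red and XHT in blue. MOD 3 lies at 10.2 on the sarcomere axis, closer to the XHT libraries (10.8 to 11.4) than to MOD 1 and MOD 2 (7.15 and 6.94), while its matrix value of 8.75 stays above the 5.33 to 6.90 of XHT.

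Of 23 calcium handling and ion channel genes, 7 rose and 0 fell (camera adjusted p = 3.17e-05; adjusted p = 0.607 with an estimated correlation). The number that rose was 1 without MOD 1 or MOD 2, 0 without XHT 1 or XHT 3, and 19 without MOD 3. Ryr2, the calcium release channel of the sarcoplasmic reticulum, rose from 42.5 ± 48.2 to 447.6 ± 168.7 CPM, and Cacna1c, the L-type calcium channel, from 25.1 ± 4.48 to 94.3 ± 34.5 CPM (SD, n = 3 each). Atp2a2, the calcium pump of the sarcoplasmic reticulum, stood at 934.6 ± 1115 and 7080 ± 1986 CPM, with an adjusted p of 0.0518 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

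Of 12 cardiac stress and fetal genes, 5 rose and 1 fell (camera adjusted p = 0.0337; adjusted p = 0.607 with an estimated correlation). Nppb, the natriuretic peptide BNP, rose from 59.9 ± 45.4 to 724.5 ± 577.4 CPM, and Rcan1, a calcineurin regulator, from 70.4 ± 32.7 to 756.9 ± 452.0 CPM (SD, n = 3 each). Ankrd1, a stretch-responsive ankyrin repeat protein, rose from 855.4 ± 744.3 to 6210 ± 2177 CPM (SD, n = 3 each). The gene that fell was Ctgf, a matricellular growth factor also on the matrix list, singled out after its values were seen. Nppa, the atrial natriuretic peptide, stood at 549.4 ± 267.0 and 1341 ± 748.3 CPM and did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.111). The number that rose was 0 without MOD 1 or XHT 1, 1 without MOD 2 or XHT 3, and 8 without MOD 3. This list did not pass without MOD 3 (adjusted p = 0.0685) or without XHT 3 (0.0554).

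Of 21 antioxidant defence genes, 10 rose, among them Cat, or catalase (log2 fold change 1.31 ± 0.30 SE), Srxn1, sulfiredoxin (2.14 ± 0.41), and the metallothionein Mt1 (2.00 ± 0.38). The 1 that fell was the cystine transporter Slc7a11, singled out after its values were seen (camera adjusted p of the list = 0.00994; adjusted p = 0.607 with an estimated correlation; fry adjusted p = 0.0479). The number that rose was 0 without MOD 1 or XHT 1 and 1 without MOD 2 or XHT 3. Hmox1, heme oxygenase 1, stood at 104.1 ± 74.4 CPM in MOD and 152.5 ± 12.4 in XHT (SD, n = 3 each), with an adjusted p of 0.389 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 5 adipocyte markers, Plin4, a lipid droplet coat protein, rose (camera adjusted p of the list = 0.0392; adjusted p = 0.607 with an estimated correlation). The adipocyte list did not pass without MOD 2 (adjusted p = 0.378), MOD 3 (0.232), XHT 1 (0.173), XHT 2 (0.109) or XHT 3 (0.124).

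**Figure D3:**
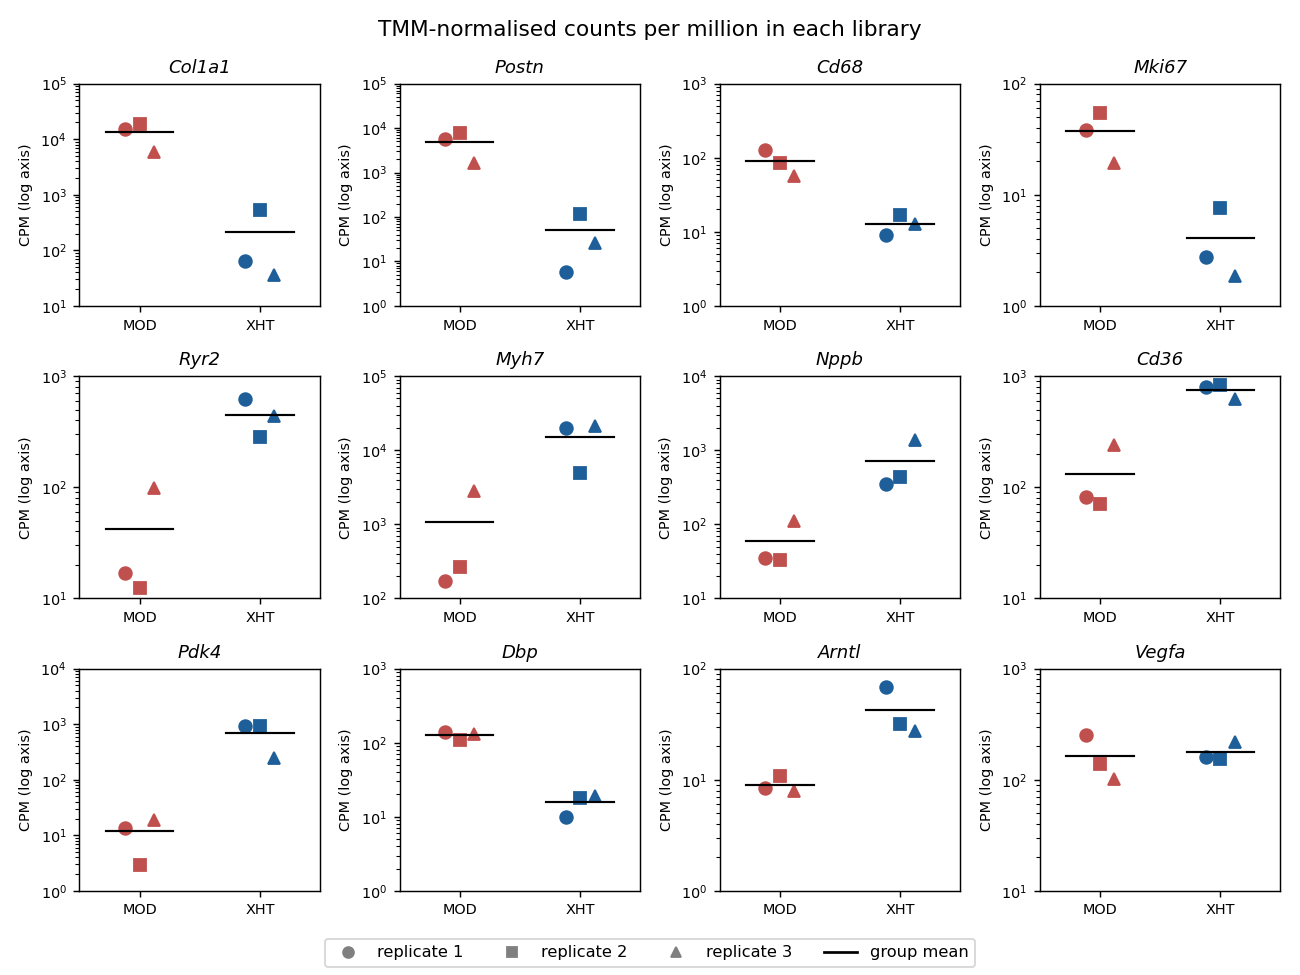
TMM-normalised CPM of 12 genes on log axes that differ between panels, 1 point per library with the replicate number as marker shape; lines are group means. Col1a1, Postn, Cd68, Mki67 and Dbp are lower and Ryr2, Myh7, Nppb, Cd36, Pdk4 and Arntl higher in all 3 XHT libraries than in any MOD library, although Myh7 did not pass the test, and Vegfa overlaps between groups.

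The remaining 19 lists did not pass camera. Of 23 coagulation, fibrinolysis and platelet genes, 7 fell, among them the platelet ADP receptor P2ry12, from 5.84 ± 0.70 to 0.76 ± 0.07 CPM. The plasminogen activator Plau fell from 18.6 ± 3.97 to 3.07 ± 1.29 CPM (SD, n = 3 each; camera adjusted p = 0.155; adjusted p = 0.607 with an estimated correlation; fry adjusted p = 0.0479). The number of coagulation genes that fell was 2 without MOD 1 or XHT 3, 4 without MOD 2 and 0 without XHT 1. Of 21 apoptosis and pyroptosis genes, 3 rose, Bcl2l1, Cflar and Xiap, which restrain cell death, and 7 fell, among them the death effector Bak1 (camera adjusted p = 0.191); Xiap was singled out after its values were seen. Without MOD 1, MOD 2 or XHT 3, 1 of these genes rose and 0 fell, without XHT 1, 0 rose or fell, and with scaling to total counts 2 rose and 12 fell. Of 19 angiogenic and growth factor genes, 2 rose, Fgf1 and Epas1, singled out after their values were seen, and 6 fell, among them Igf1 and Figf (camera adjusted p = 0.405). Without MOD 1, MOD 2 or XHT 3, 0 rose and 2 fell, and without XHT 1, 0 rose or fell. Vegfa stood at 164.6 ± 78.8 CPM in MOD and 177.5 ± 36.4 in XHT (adjusted p = 0.833 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 17 endoplasmic reticulum stress genes, 4 rose and 5 fell (camera adjusted p = 0.493). With scaling to total counts, 2 rose and 9 fell, without MOD 1 or XHT 1, 0 rose or fell, and 0 fell without MOD 2 or XHT 3. Of 18 renin-angiotensin, endothelin and adrenergic genes, 2 rose, Ece1 and Adra1a, and 2 fell, Agtr1a and Ednra (0.729). In this list 0 rose or fell without MOD 1, MOD 2, XHT 1 or XHT 3, 5 rose and 4 fell without MOD 3, and 0 rose and 3 fell with scaling to total counts.

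Of 16 circadian clock genes, Arntl, Cry1 and Cry2 rose and Dbp, Per3 and Bhlhe41 fell (camera adjusted p = 0.904); Cry1 and Cry2 were singled out after their values were seen. In this list 0 rose and 1 fell without MOD 1 or XHT 1, and 1 rose and 1 fell without MOD 2. Dbp, a clock output transcription factor, fell from 125.7 ± 15.1 to 15.8 ± 5.09 CPM, and Arntl, which encodes the clock activator BMAL1, rose from 9.02 ± 1.58 to 42.4 ± 22.5 CPM (SD, n = 3 each). Of 20 immediate early genes, Fosl2 and Btg2 rose (camera adjusted p = 0.526), of 9 heat shock genes Bag3 rose (0.493), and of 4 sex-linked genes 0 differed (0.786). Without MOD 1 or XHT 1, 0 immediate early or heat shock genes rose. Without MOD 2, 0 immediate early genes rose, and without XHT 2, 4 rose and 1 fell. Without XHT 3, 0 rose and 1 fell, and the median log2 fold change of the immediate early list went from 0.46 to -0.45.

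Among markers of other cell types, Flt1 and Nos3 rose and Emcn fell of 15 endothelial markers (camera adjusted p = 0.246). Of 12 smooth muscle and pericyte markers, Acta2, Tagln and Pdgfrb fell (0.364), and of 11 lymphocyte markers, Cd4, Cd8a and Cd8b fell (0.493). With scaling to total counts, 6 smooth muscle markers fell. Of 7 atrial markers, Myl7 and Pam rose and Dkk3 fell (0.0668). Of 8 neutrophil markers Il1r2 rose (0.155). Of 5 red blood cell markers, Hbb rose (0.0931), to 514.8, 1838 and 168.8 CPM in XHT 1, 2 and 3 against 183.1, 77.0 and 46.2 in MOD 1, 2 and 3. Of 8 mast cell markers, Tpsab1 rose and Kit fell, and Mcpt2 had 38 counts in MOD and 0 in XHT, at least 9.86-fold lower with a floor of 3 counts over the group (camera adjusted p of the list = 0.875). Of 8 Schwann cell and neuronal markers, Cdh19 rose and Ngfr and Prph fell (0.421), and of 6 mesothelial and epicardial markers, Aldh1a2 fell (0.304). XHT 2 stood apart in the mesothelial list, with a mean log2 CPM of 3.71 against -0.39 and -0.24 in XHT 1 and XHT 3, and without XHT 2, 5 of the 6 fell. Of 3 skeletal muscle markers, Tnnt3 fell (0.997), and this list's median and mean log2 fold changes, -0.09 and -0.24, were negative where camera gave the direction as up. Without MOD 1, MOD 2, XHT 1 or XHT 3, at most 1 member of each list in this paragraph was called. Without MOD 3, some lists had more calls: 6 endothelial markers rose and 1 fell, and 4 atrial markers rose and 1 fell. In that fit 1 smooth muscle marker rose and 5 fell. The atrial list passed without XHT 1 (adjusted p = 0.00225), the mesothelial list without XHT 2 (0.00185), the neutrophil list without MOD 2 (0.00569) or XHT 3 (0.0267). The red blood cell list passed without MOD 1 (0.0320), XHT 1 (0.0423) or XHT 3 (0.0267).

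By p-value, the genes that differed most clearly included Aldh1a3, a retinoic acid synthesis enzyme, which fell from 28.2 ± 6.23 to 1.95 ± 0.29 CPM. Kcnv2, a modifying potassium channel subunit, fell from 29.2 ± 7.14 to 1.36 ± 0.36 CPM, and Cybb, an NADPH oxidase subunit of phagocytes, from 205.4 ± 34.8 to 27.5 ± 4.52 CPM. Among those that rose were Galnt15, from 2.39 ± 0.85 to 26.5 ± 4.84 CPM, and Fam107a, an actin-associated stress-responsive protein, from 32.1 ± 7.59 to 191.0 ± 23.7 CPM (SD, n = 3 each). Of the 135 named genes that passed, 6 kept the call in every alternative in which they were tested. These were Capn6, Fam134b, Dbp, Aldh1a3, Kcnv2 and 1 locus without a gene symbol, which was not part of the fit on protein-coding genes only.

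The identifiers and positions in the authors' deposited table, whose genome build is not given in the sources used here, place Capn6 (ENSRNOG00000004882) on chromosome X at 115049154 to 115073890. Col1a1 (ENSRNOG00000003897) lies on chromosome 10 at 82745801 to 82762789, and Postn (ENSRNOG00000012660) on chromosome 2 at 143656793 to 143688087. Pdk4 (ENSRNOG00000009565) lies on chromosome 4 at 30546664 to 30556814, and Nppb (ENSRNOG00000008141) on chromosome 5 at 164796185 to 164797531. Dbp (ENSRNOG00000021027) lies on chromosome 1 at 101687855 to 101692846. All are annotated as protein coding.

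In the authors' deposited table, 2635 genes were higher and 2699 lower in XHT at the authors' adjusted p under 0.05. The sign of the fold change was the same in the authors' deposited table and in the edgeR fit for 98.4% of the 14488 tested genes, and 4084 of the 4128 genes called by edgeR were also past the threshold there.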

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

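The settings with total-count scaling and without mitochondrial genes were chosen after seeing the data. No called gene changed sign in the settings given here. Genes higher in XHT ranged from 4 (without XHT 1) to 3487 (without MOD 3) and genes lower from 4 to 3421 when single libraries were left out, with 128 and 375 without MOD 1, 227 and 570 without MOD 2, and 148 and 288 without XHT 3. Those fits have fewer samples; why XHT 1 had the largest effect was not tested, and at an unadjusted p under 0.05 the fit without it still held 5002 genes, against 6507 with all libraries. DESeq2's Wald test called 2718 higher and 2743 lower, with 37 adjusted p-values not given. Total-count scaling called 925 higher and 4320 lower, with the median of all genes at -0.42; by construction it leaves out the TMM factors. DESeq2 size factors, no count filter, the legacy fit, protein-coding genes only and no mitochondrial genes each stayed within 1.5 times of both counts. Lists past the threshold numbered 12 to 17 when single libraries were left out, 0 with an estimated correlation and 4 by fry. With total-count scaling the atrial, neutrophil and red blood cell lists passed as well, and without a count filter the atrial list passed and the adipocyte list did not, its median log2 fold change going from 0.95 to -0.90 while camera's direction stayed up. Whether the replicate numbers pair the samples cannot be settled with groups of 3. Same-numbered libraries correlated at -0.07, 0.25 and 0.12 in their deviations from the group means. The value for MOD 2 with XHT 2 was the highest of all pairs, but MOD 1 also correlated best with XHT 2 and MOD 3 with XHT 1. With the replicate block, 2101 genes were higher and 2309 lower, 3678 of them shared with the fit without it, and 18 lists passed. Sarcomere genes called higher went from 1 to 13 with the block, and oxidative phosphorylation genes from 7 to 23. Fatty acid oxidation genes called higher went from 14 to 24, and matrix genes called lower from 29 to 28. Of genes changed 4-fold in simulation 53% were called, at a stricter cut on p than in the data because fewer genes were changed. That share does not carry over to the data. With 3 libraries per group, a gene that did not pass is still not shown to be the same in both groups.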

Other observations

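Genes known as glucocorticoid and FOXO targets in muscle formed a group that no fixed list covered as such, although Pdk4, Mt1, Mt2A and Per1 stand on other lists. Of 18 such genes, 10 were higher in XHT and 0 lower: Trim63, a muscle ubiquitin ligase, rose from 22.4 ± 11.9 to 399.7 ± 242.8 CPM, Fkbp5, a chaperone of the glucocorticoid receptor, from 49.2 ± 14.9 to 266.1 ± 41.3 CPM, and Cdkn1a, the cell cycle inhibitor p21, from 42.1 ± 4.37 to 309.7 ± 121.1 CPM (SD, n = 3 each). Klf15, Klf9, Fbxo32, Txnip, Pdk4, Mt1 and Mt2A were the others, and Zbtb16, Sgk1, Per1, Tsc22d3, Cebpd, Pik3ip1, Gadd45a and Angptl4 did not pass. The number higher was 3 without MOD 1, 7 without MOD 2, 13 without MOD 3, 0 without XHT 1, 8 without XHT 2, where 1 was lower, and 5 without XHT 3. The list was written after the values of these genes, and of 9 more that were left out of it, had been seen, so its direction is not independent evidence.

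The tests of the 3 patterns were chosen after the result was seen, and those on other splits of the samples before; 1 covariate was tried.

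The first pattern was the fall of matrix genes beside the higher sarcomere values. A lower share of muscle cells in the MOD pieces that raised every other cell type alike is argued against. Such a shift needs the same endothelial minus macrophage marker score in both groups, and it was 2.17 ± 0.43 log2 units (SE) higher in XHT. Both lists had been seen when this test was written, and it covers only an even rise. The score was 0.17, 0.26 and 1.40 in MOD 1, 2 and 3, highest in the MOD library with the highest sarcomere score. It therefore does not argue against uneven differences in cell content. More scar and less muscle in the MOD pieces stays open. With the sarcomere score as a covariate the median matrix log2 fold change went from -3.36 to -1.78, while the median SE was 0.56 in both fits. The called members went from 29 to 0 and the fry p from 0.00404 to 0.0587, with 23 of the 32 still at an unadjusted p under 0.05. In the same fit the median of the macrophage markers went from -1.75 to -1.21 and their fry p from 0.00135 to 0.0264, with 11 of 17 at an unadjusted p under 0.05. Over all genes the calls went from 4128 to 7, and 4103 of the 4128 kept their sign; why calls were lost was not tested. Whether muscle content explains the rises in the metabolic, calcium and stress lists was not tested and stays open. Treatment, infarct size and the part of the heart sampled cannot be told apart here, because the labels give only the first.

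The second pattern was a shift of clock genes, with Arntl and Cry1 higher and Dbp, Per3 and Bhlhe41 lower in XHT. The fixed clock list did not pass camera, and the signed list of 14 phase genes used here was written after clock genes had been looked at. Of the fixed clock list it left out Cry2, also called higher, and Per1 and Bhlhe40, which were not called. Per1 had a log2 fold change of 0.66, against the direction of Per2 and Per3. Nfil3 was added, with a log2 fold change of 1.44 in the direction of the shift, and was not called. Muscle content stays open: the signed fry p of the 14 genes was 0.0211 before and 0.120 with the sarcomere score in the fit. Their median signed log2 fold change did not shrink, at 0.37 before and 0.70 with the score, while the median SE rose from 0.36 to 0.62, and the called genes went from 5 to 0. Dbp alone, the gene with the largest change, stood at -2.99 ± 0.29 before and -3.02 ± 0.40 with the score (log2 fold change ± SE); a top gene excludes nothing for the set. A second test, run after that result was known and on the 5 called genes alone, gave a fry p of 0.0317 and a median signed log2 fold change of 1.62 before and 1.65 with the score; as a second try on genes picked for the pattern, it excludes nothing. Hearts taken at another time of day may also give this shift, with 5 phase genes called in the direction of 1 shift and 0 against it, and cannot be told apart from the treatment because no sampling time is given. The phase genes called in that direction numbered 1 without MOD 1 or XHT 1, 2 without MOD 2 and 5 without MOD 3. They numbered 6 without XHT 2 and 4 without XHT 3, with 0 called against it in each. Counting uncalled genes too, 12 of the 14 went in that direction, while Npas2 (log2 fold change -0.70) and Nr1d1 (0.38) went against it. Tef, Per2, Ciart and Clock changed little (-0.05, -0.11, -0.14 and 0.15), so the shift was uneven over the phase genes.

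The third pattern was the glucocorticoid and FOXO target list. Muscle content as its cause stays open. The fry p was 4.31e-04 before and 0.00439 with the sarcomere score in the fit, and with the genes left out of the list added it was 4.51e-04 before and 3.43e-04 with the score, while the median of that wider list fell from 1.78 to 1.06. A test on genes picked after their values were seen excludes nothing. The median log2 fold change of the 18 genes went from 1.89 to 1.36, with the median SE rising from 0.40 to 0.62, and the called members went from 10 to 0. Fasting, stress or time of sampling was not tested and stays open beside the treatment.

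For the counts of genes and lists, the 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split called 4128 genes and the highest of the others 0, so 1 of the 10 splits gave as many. It gave 16 lists by camera, and the split that set MOD 1, MOD 2 and XHT 1 against the rest also gave 16. So 2 of the 10 splits gave as many. The other splits gave 8 to 13 lists each, with 0 genes called. Passing camera with the preset correlation therefore does not set the real groups apart from mixed ones. Each mixed split still kept most MOD libraries on one side and most XHT libraries on the other, so part of the real difference stayed in it. The splits cannot show how many lists unchanged groups would give.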
